A study of Homo sapiens with 8 samples.

How the data were processed

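Total RNA of tumours of the human breast cancer line BT474 was measured in 8 samples, 1 Affymetrix human expression array each, 4 of tumours grown in the mouse brain and 4 of tumours grown in the mammary fat pad. BT474 is an oestrogen receptor positive line with an amplified ERBB2 gene. Per the labels' protocols, tumours were snap frozen, RNA was extracted with a column kit and labelled with biotin. The deposited values are log2 expression values per probe set, 1 column per array. Per the submitters' processing notes they were made with RMA, which corrects background, normalizes by quantiles and summarizes the probes of a probe set, in the affy package, whose version is not given in the sources used here. The array medians lay between 6.77 and 6.81 (log2), and no further normalization was applied. The lowest value of an array lay between 3.32 and 3.41 and the highest between 14.88 and 14.99, and differences of genes near either end can be understated. An array has no read depth, and the number of arrays limits the precision.

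The table held 54675 probe sets, of which 62 were controls. The platform annotation used here paired 41097 with exactly 1 gene and 1801 with several, and did not list 11777, which stay unnamed here. Symbols were updated through the Entrez identifier, which matched for 41043 probe sets. For each of 19775 genes, the probe set with the highest mean over the 8 arrays was used. No genome build is named for these values, so no coordinates are given. Human probes can also bind mouse transcripts, and the array does not separate tumour from host RNA.

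Groups and replicate numbers come from the sample titles. The comparison, the tests, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where stated. Brain was compared with mammary fat pad with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust). Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested are called, and differences are brain minus mammary fat pad on the log2 scale with the moderated standard error. All 32 fixed gene lists had at least 5 measured members and were tested with camera in limma, with a preset correlation between genes of 0.01. camera asks whether a list moved relative to all other genes, and its adjusted p is over the 32 lists. It was repeated with an estimated correlation. fry, which asks whether the genes of a list move on balance in one direction, was a further alternative. After the data were seen, the mean of each list on each array was also compared by an exact two-sided permutation test, whose smallest p with 4 against 4 arrays is 0.0286. Members of a list were counted both over all genes tested and adjusted over the list alone.

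Named genes are the 10 called genes with the largest difference in each direction, without overlap between the groups and at a mean of at least 6 in the higher group. The 6 largest per direction outside the host cell lists, the HER receptor genes with ESR1, PGR and any called HER ligand, and up to 4 members with the smallest p per list were added. Genes named outside this rule are said to be so where they appear.

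The procedure was tested on 5 simulated data sets of 19775 genes for the comparison of brain with mammary fat pad, each with 200 changed genes. It called 78% of genes changed by 0.5 log2, 96.8% of those changed by 1 and 100% of those changed by 2, and 4.67% of calls were unchanged genes. A list shifted by 0.3 was called in 5 of 5 data sets, and 0 other lists were called. The changes of 2 were all decreases. The simulated genes were independent, with normal noise and no effects shared by the genes of an array. The test thus says nothing about correlated lists, and its shares for genes need not hold for these data.

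Array quality was described by the median, the correlation between arrays, principal components of the genes, and the difference between 3' and 5' control probe sets of GAPDH and ACTB. No pair of arrays held the same values, and the SD of the difference between 2 arrays ran from 0.155 to 0.320. Alternatives covered the replicate number as a block, each array left out, other scalings, filters on dim genes, other ways to choose probe sets, other variance models and other list tests. Plots were drawn with matplotlib 3.10.9.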

Results

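Gene expression was measured in xenografts of BT474, a human breast cancer line with amplified ERBB2, grown either in the brain or in the mammary fat pad of mice. There were 4 arrays per site. The comparison asks how the site of growth relates to expression in the tumour tissue. Nothing in the labels says that the replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

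APOD and PIP had the largest increases in brain tumours. APOD, a lipid-carrying lipocalin, was 9.72-fold higher in the brain (difference 3.28 ± 0.63 log2, SE, n = 4 per site), and PIP, the prolactin-induced protein, was 6.96-fold higher (2.80 ± 0.54). Single arrays moved both values: APOD differed by 2.68 without brain replicate 2 and by 3.95 without brain replicate 4, and PIP by 3.48 without brain replicate 4. The secretoglobin SCGB2A1 rose by 1.94 ± 0.35 and the mucin-like MUCL1 by 1.63 ± 0.19, from an already high level of 13.06 to 14.69. The brain level lies near the top of the array's range, so the MUCL1 difference can be understated. The protease inhibitor CSTA rose by 2.16 ± 0.39, the metal ion importer SLC39A8 by 2.05 ± 0.22, the protein kinase A subunit PRKAR2B by 2.03 ± 0.33, and NDST4, an enzyme of heparan sulphate synthesis, by 1.73 ± 0.13. HOPX, a homeodomain protein, rose by 1.70 ± 0.33, and 1 probe set of the non-coding RNA MALAT1 rose by 1.81 ± 0.20, while 2 other MALAT1 probe sets fell (-2.47 and -3.38) and the mean of all 12 differed by -0.53 without being called. NDST4 had the smallest adjusted p of these genes (limma, 0.0011), and HOPX the largest (0.0394). In each of them all 4 brain arrays lay above all 4 mammary fat pad arrays.

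CXCL14 had the largest decrease in brain tumours. This chemokine was 7.10-fold lower in the brain (-2.83 ± 0.28 log2, SE, n = 4 per site), at 5.50 against 8.33. The fibrillar collagen COL3A1 differed by -2.56 ± 0.41, the matrix glycoprotein TNC by -1.51 ± 0.27, and LOXL1, which crosslinks matrix fibres, by -1.45 ± 0.26. ANXA1, a membrane-binding annexin, differed by -2.32 ± 0.47 (-2.91 without brain replicate 4) and S100A4, a calcium-binding protein, by -1.65 ± 0.23. SULF2, a sulphatase that edits heparan sulphate, differed by -1.47 ± 0.16, CEACAM5, the carcinoembryonic antigen, by -1.38 ± 0.20, CPED1 by -1.70 ± 0.28 and KCTD12 by -1.44 ± 0.29. ANXA1 had the largest adjusted p of these genes (limma, 0.0440) and CXCL14 the smallest (0.0031).

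**Figure D1:**
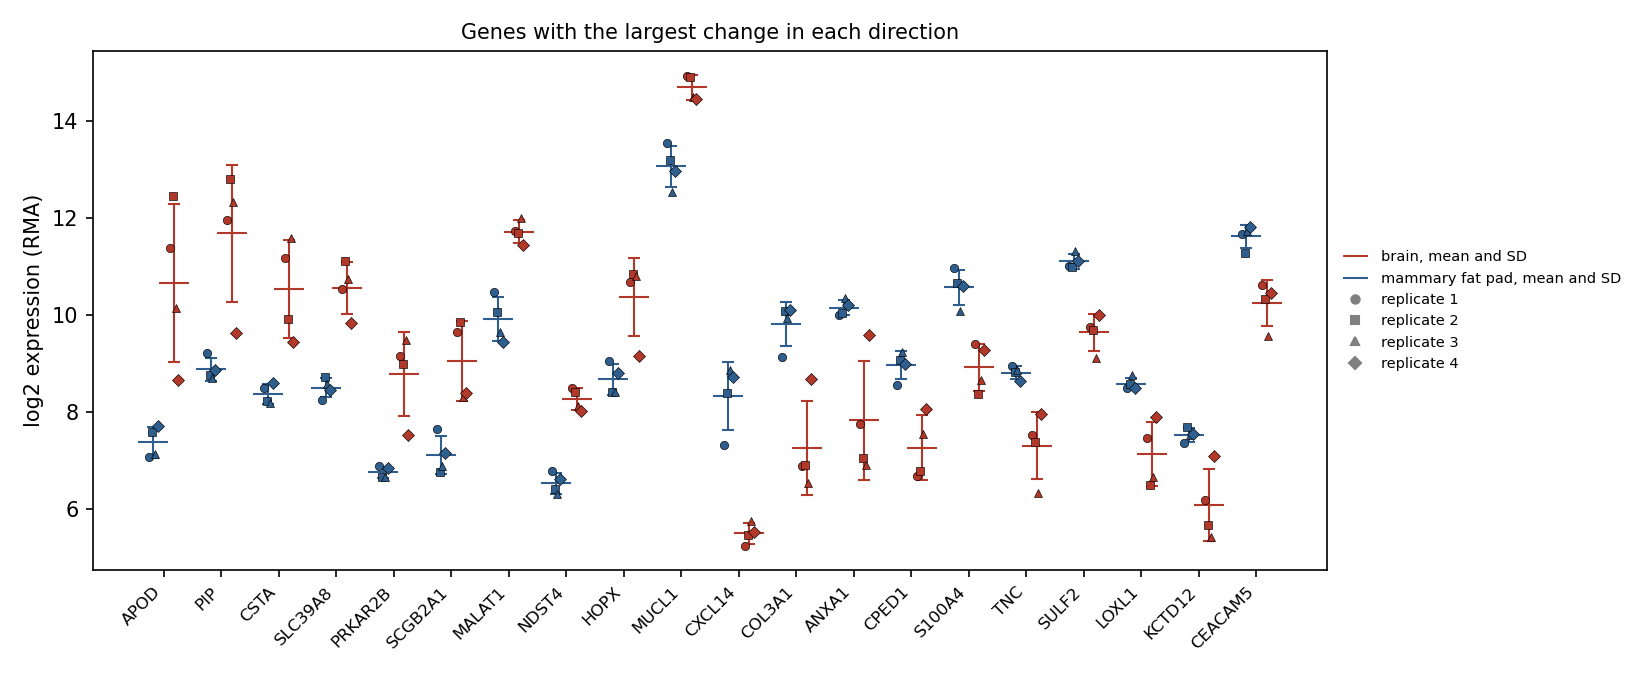
Log2 expression of the 10 genes with the largest increase and the 10 with the largest decrease in brain tumours, 1 point per array, with the mean and SD of the 4 arrays per site. APOD ran from 8.65 to 12.45 in the brain arrays and from 7.07 to 7.71 in the mammary fat pad arrays, and CXCL14 lay at a mean of 5.50 against 8.33.

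In all, 278 of 19775 genes were called, 179 higher and 99 lower in brain tumours, and 43 of them differed by 2-fold or more, 24 higher and 19 lower (limma, Benjamini-Hochberg adjusted p under 0.05). In all 278 the brain and mammary fat pad values did not overlap. At an unadjusted p under 0.05 there were 3258 genes. The groups did not overlap in 1901 genes, 9.61% of those tested, where chance gives 2.86%. The number of calls depended on single arrays: it was 84, 64 and 1005 without brain replicates 1, 2 and 4, and 129, 64, 53 and 33 without mammary fat pad replicates 1, 2, 3 and 4. The count at 2-fold or more was 17, 18 and 110 without brain replicates 1, 2 and 4, and 17, 16 and 13 without mammary fat pad replicates 2, 3 and 4. Of the 278 genes, 82, 64, 199 and 278 stayed called without brain replicates 1 to 4, and 112, 64, 53 and 33 without mammary fat pad replicates 1 to 4. Called in each of those 8 fits were 6 of the 20 largest changes, SLC39A8, MALAT1, NDST4, MUCL1, CXCL14 and SULF2. S100A4 was called in 7 of these 8 fits, CEACAM5 in 6, SCGB2A1, COL3A1 and CPED1 in 3, APOD, CSTA, PRKAR2B, TNC, LOXL1 and KCTD12 in 2, and PIP, HOPX and ANXA1 in 1. Of the called list members in the paragraphs below, SERPINA1, VIM, ACSL1 and POSTN were called in all 8 fits and the others in fewer. With a trend and robust variance 12 of the 20 were not called: APOD (adjusted p = 0.117), PIP (0.119), CSTA (0.0952), PRKAR2B (0.0698), SCGB2A1 (0.0882), HOPX (0.103), COL3A1 (0.0699), ANXA1 (0.130), CPED1 (0.0579), TNC (0.0700), LOXL1 (0.0695) and KCTD12 (0.101). An equal-variance test per gene called 0 genes after adjustment and 2749 at an unadjusted p under 0.05. The share of calls higher in the brain was 64.4%, 51.6% after quantile normalization, and 86.7% after centring on tumour cell genes, which moved the median of all genes by 0.133, from 0.0035 to 0.136. The tumour cell genes are those of the HER2 amplicon and luminal epithelium lists, whose median is set equal across arrays. Probe sets of 1 gene did not always move together: without the probe set types that can bind several transcripts, the differences were -0.14 for HOPX, -0.35 for MALAT1, 0.070 for CXCL14 and 0.09 for COL3A1, and none of these was called. With the mean of all probe sets, HOPX (0.43), TNC (-0.57) and KCTD12 (-0.97) were not called. Another COL3A1 probe set was at -1.36 (limma over all probe sets, adjusted p = 0.0558).

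Some genes of lipid synthesis rose in brain tumours. Of 16 measured genes of fatty acid synthesis 5 were called higher and 0 lower over all genes tested, and 9 were higher adjusted over the list alone. ACSL1, which activates fatty acids, rose by 0.76 ± 0.08 (SE, n = 4 per site), the fatty acid synthase FASN by 0.75 ± 0.11, the desaturase FADS2 by 0.60 ± 0.11, and ACSS2, which makes acetyl-CoA from acetate, by 0.34 ± 0.07. Of 17 cholesterol synthesis genes 3 were called higher and 0 lower, SC5D by 0.67 ± 0.10, LSS by 0.49 ± 0.08 and IDI1 by 0.50 ± 0.09. Adjusted over the list alone 7 were higher. INSIG1, which restrains the pathway, was at 10.81 ± 0.35 in the brain and 10.21 ± 0.14 in the mammary fat pad (SD, n = 4) and was not called. Both lists were higher by camera (adjusted p = 2.6e-06 for each). The list means of the 4 brain arrays lay above those of all mammary fat pad arrays (exact permutation p = 0.0286, unadjusted). For cholesterol synthesis the gap was narrow, with brain replicate 3 at 9.910 and mammary fat pad replicate 3 at 9.902. The adjusted p with an estimated correlation was 0.0826 for fatty acid synthesis and 0.401 for cholesterol synthesis. The number of members called over all genes tested depended on single arrays. For fatty acid synthesis it was 6 without brain replicate 4, 5 without mammary fat pad replicate 1, 4 without brain replicate 3, 2 without brain replicate 1 or mammary fat pad replicate 2, and 1 without brain replicate 2 or mammary fat pad replicate 3 or 4. For cholesterol synthesis it was 4 without brain replicate 3, 3 without brain replicate 4, 2 without mammary fat pad replicate 1, 1 without brain replicate 1 or 2 or mammary fat pad replicate 2 or 3, and 0 without mammary fat pad replicate 4. Without the probe set types that can bind several transcripts, SC5D differed by 0.069, FADS2 by 0.10 and IDI1 by -0.024, each read by a dimmer probe set, and none of the 3 was called. Another IDI1 probe set differed by 0.47. With the mean of all probe sets, LSS (0.42), IDI1 (0.27), FASN (0.38) and FADS2 (0.35) were not called. INSIG1 was called after centring on tumour cell genes (0.73, limma adjusted p = 0.0018).

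TAPBP, a chaperone of peptide loading, rose by 0.34 ± 0.06 (SE, n = 4 per site) and B2M, the light chain of MHC class I, by 0.69 ± 0.14, the 2 of 14 MHC class I genes that were called. None of the 14 was called lower, 12 had a positive difference and 2 a negative one, and 7 were higher adjusted over the list alone. The list was higher by camera (adjusted p = 0.000414), and its adjusted p with an estimated correlation was 0.529. Its means did not overlap between the sites (exact permutation p = 0.0286, unadjusted). The gap was narrow, with brain replicate 4 at 9.150 and mammary fat pad replicate 2 at 9.142. Of 27 interferon response genes 24 had a positive difference and 3 a negative one, but only PARP9 was called, higher by 1.12 ± 0.21. Adjusted over the list alone 2 were higher. The list had a camera adjusted p of 0.00062, and 0.693 with an estimated correlation. HERC6 was at 8.47 ± 0.56 in the brain against 7.45 ± 0.14 (SD, n = 4) and was not called, but was without brain replicate 3 (0.78, limma adjusted p = 0.0325) or 4 (1.23, adjusted p = 0.0040). The interferon list mean was 7.68 in brain replicate 3 and 6.92 to 7.24 in the other brain arrays, and its means overlapped (exact permutation p = 0.0857). Without brain replicate 1 or 2, or any 1 mammary fat pad array, 0 members of either list were called by limma. Without brain replicate 3, 1 MHC class I gene and 1 interferon gene were called, and without brain replicate 4, 4 and 4. With probe sets that can bind several transcripts left out, B2M differed by -0.034 and PARP9 by -0.011, and with the mean of all probe sets B2M (0.40) and TAPBP (0.29) were not called. Nor were PARP9 (adjusted p = 0.0650) and B2M (0.0548) with a trend and robust variance. The B2M probe set of that reading lay near the bottom of the array, at 4.43 against 4.47, and another B2M probe set, at 12.51 against 11.96, differed by 0.55 (limma over all probe sets, adjusted p = 0.0510).

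The collagen genes COL3A1, COL1A2 and COL1A1 fell in brain tumours. Of 20 fibroblast and matrix genes 4 were called lower and 0 higher: COL3A1 as above, COL1A2 by 1.32 ± 0.21 (SE, n = 4 per site), COL1A1 by 0.54 ± 0.09 and POSTN, a matrix protein measured near the bottom of the array's range, by 0.88 ± 0.08. Adjusted over the list alone, 7 fell. Of 10 basal epithelial genes TRIM29 fell by 0.59 ± 0.08 and CDH3, the P-cadherin, by 0.62 ± 0.11, and 6 fell adjusted over the list alone. Among 19 genes that the ERK pathway induces, the transcription factors ETV5 and ETV4 fell, by 0.66 ± 0.13 and 0.43 ± 0.09, and 3 fell adjusted over the list alone. SPRED1, a feedback inhibitor of the pathway, was at 7.40 ± 0.61 against 8.43 ± 0.19 (SD, n = 4) and was not called, but was without brain replicate 4 (-1.27, limma adjusted p = 0.0055). All 3 lists were lower by camera (adjusted p = 2.6e-06, 6.2e-05 and 0.000141 in this order), with means that did not overlap (exact permutation p = 0.0286 for each, unadjusted). With an estimated correlation the adjusted p was 0.270, 0.103 and 0.174. Of matrix genes 5 were called without brain replicate 3 or 4, 3 without mammary fat pad replicate 1, 2 without brain replicate 1 or 2, and 1 without mammary fat pad replicate 2, 3 or 4. Of basal genes 2 were called without brain replicate 3 or 4, 1 without brain replicate 1 or 2 or mammary fat pad replicate 1, 2 or 3, and 0 without mammary fat pad replicate 4. Of ERK pathway genes 3 were called without brain replicate 4, 1 without brain replicate 2 or 3, and 0 without brain replicate 1 or any 1 mammary fat pad array. With the mean of all probe sets, COL1A2 (-0.44), COL1A1 (-0.18), POSTN (-0.23), TRIM29 (-0.33), ETV5 (-0.31) and ETV4 (-0.46) were not called. Nor were COL1A2 (-0.13), ETV5 (-0.56) and ETV4 (-0.49) without probe sets that can bind several transcripts. The other COL1A2 probe sets differed by -0.13 and 0.14 and were not called, and brain replicate 4 was the highest brain array for this gene, at 8.17 against 7.20 to 7.35.

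Of 12 regulators of epithelial to mesenchymal transition, only the intermediate filament gene VIM was called, lower by 0.73 ± 0.09 (SE, n = 4 per site), and 1 was lower adjusted over the list alone. SNAI2 was at 4.26 ± 0.06 in the brain and 4.41 ± 0.02 in the mammary fat pad (SD, n = 4), near the bottom of the range. The list was lower by camera (adjusted p = 0.0095), but its adjusted p was 0.330 with an estimated correlation and 0.0541 without brain replicate 4, and the array means overlapped (exact permutation p = 0.114).

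Hypoxia, proliferation and PI3K pathway genes were called as lists without any member being called over all genes tested (camera adjusted p = 0.0032, 0.000164 and 0.0164 in this order). With an estimated correlation the adjusted p was 0.693, 0.693 and 0.401. Of 18 hypoxia response genes, 16 had a positive difference with a median of 0.39, among them DDIT4 at 11.95 ± 0.18 against 10.91 ± 0.86, BNIP3 at 10.23 ± 0.36 against 9.11 ± 1.003 and ADM at 8.78 ± 0.93 against 7.44 ± 1.01 (SD, n = 4). The large spread in the mammary fat pad came from replicate 1, whose list mean was 9.89 where the other 3 lay between 8.61 and 8.66 and the brain arrays between 9.06 and 9.71. Without that array 5 hypoxia genes were called, among them BNIP3 by 1.61 (limma adjusted p = 0.0092) and DDIT4 by 1.44 (adjusted p = 0.0157). Of 28 proliferation genes 24 had a negative difference, with a median of -0.17, and MCM7 was at 11.26 ± 0.22 against 11.57 ± 0.13 and AURKB at 8.45 ± 0.25 against 8.75 ± 0.07. The proliferation list mean differed by -0.156, by -0.065 without brain replicate 3 and by -0.240 without brain replicate 4. In brain replicate 4 that mean was 10.425, above every mammary fat pad array (10.24 to 10.39). Of 22 PI3K, AKT and mTOR components, 15 had a positive difference, with PIK3R3 at 11.07 ± 0.36 against 10.51 ± 0.13 and AKT2 at 10.54 ± 0.11 against 10.28 ± 0.08. Adjusted over the list alone, 2 PI3K components were higher, and 0 hypoxia and 0 proliferation genes passed. At an unadjusted limma p under 0.05 there were 5 hypoxia, 5 proliferation and 8 PI3K pathway genes. Without brain replicate 4, 1 hypoxia gene was called higher, 2 proliferation genes lower, and 4 PI3K components higher and 1 lower, among them AURKB (-0.41, limma adjusted p = 0.0204), PIK3R3 (0.69, adjusted p = 0.0200) and AKT2 (0.31, adjusted p = 0.0333).

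The array means of the hypoxia, proliferation and PI3K lists overlapped between the sites (exact permutation p = 0.229, 0.286 and 0.0857). The camera calls ended without brain replicate 1 for hypoxia (adjusted p = 0.0574) and the PI3K components (0.169), and without brain replicate 3 for proliferation (0.0884). In all, 11 of 32 lists were called with the preset correlation, 6 higher and 5 lower, and 0 with an estimated one, where 4 had an unadjusted p under 0.05. fry called 3.

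**Figure D2:**
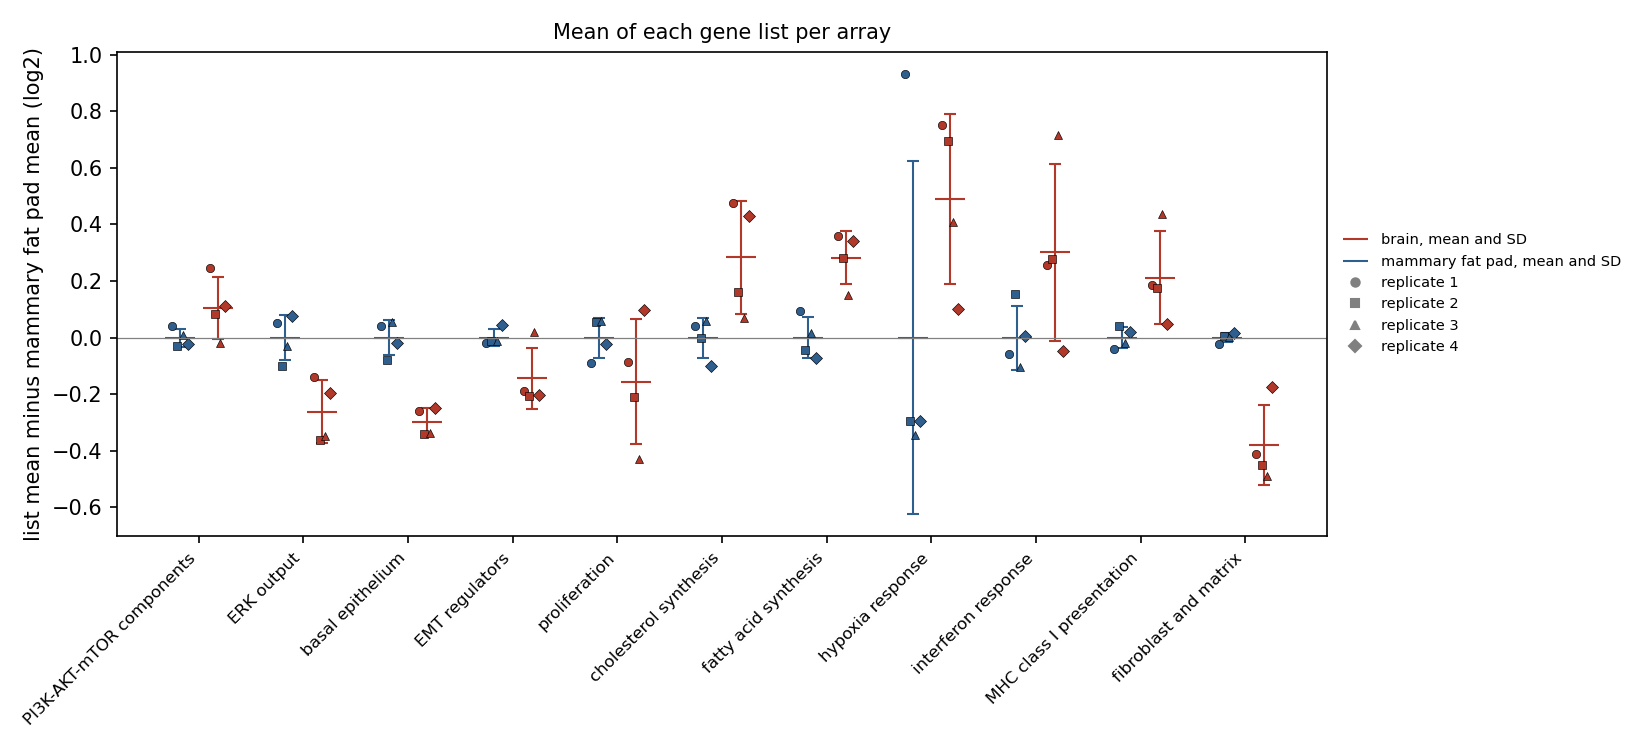
Mean log2 expression of each called gene list on each array, minus the mean of the 4 mammary fat pad arrays, with the mean and SD per site. The sites did not overlap for ERK output, basal epithelium, cholesterol synthesis, fatty acid synthesis, MHC class I presentation and fibroblast and matrix genes. The gap was narrow for cholesterol synthesis and MHC class I presentation. Mammary fat pad replicate 1 lay above all brain arrays for hypoxia response.

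The HER receptor genes were not called. ERBB2, the amplified receptor of this line, was at 14.37 ± 0.16 in the brain and 14.35 ± 0.07 in the mammary fat pad (SD, n = 4). Its difference was 0.03 ± 0.08 (SE, limma adjusted p = 0.907). Both levels lie near the top of the array's range, so an ERBB2 difference can be understated. ERBB3 was at 10.87 ± 0.13 against 10.74 ± 0.08 (adjusted p = 0.466) and ERBB4 at 7.24 ± 0.38 against 7.66 ± 0.21 (adjusted p = 0.253). EGFR was at 10.33 ± 0.52 against 9.23 ± 0.96 (adjusted p = 0.218). Mammary fat pad replicate 1 had an EGFR value of 10.66 and the other 3 lay between 8.59 and 8.90. Without it EGFR was called at 1.57 ± 0.24 (SE; adjusted p = 0.0291), as it was after centring on tumour cell genes (1.23 ± 0.28, adjusted p = 0.0086). Of the 8 other EGFR probe sets, 4 were at 0.81, 0.51, 0.41 and 0.41, 2 near 0 at -0.031 and -0.0098, and 2 at -0.87 and -0.84. None of them was called. For ERBB2, 1 other probe set differed by 1.97 ± 0.71 with an SD of 1.67 among mammary fat pad arrays (adjusted p = 0.239), and the other by 0.01.

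Among 13 measured HER receptors and ligands 0 were called over all genes tested, 6 had an unadjusted limma p under 0.05, and adjusted over the list alone 2 were higher and 2 lower. The ligand BTC was at 5.57 ± 0.52 against 6.44 ± 0.31 and EGF at 6.58 ± 0.22 against 6.21 ± 0.12 (SD, n = 4). Without brain replicate 4 both were called, BTC at -1.08 (limma adjusted p = 0.0140) and EGF at 0.45 (adjusted p = 0.0384). The steroid receptor genes ESR1, at 9.71 ± 0.49 against 9.03 ± 0.21 (adjusted p = 0.136), and PGR, at 10.34 ± 0.90 against 10.29 ± 0.20 (adjusted p = 0.963), were not called either. ESR1 was called after centring on tumour cell genes (0.81 ± 0.19, SE, limma adjusted p = 0.0101). That set includes ESR1, and the centring raised the median difference of all genes by 0.133. The receptor and ligand list was not called (camera adjusted p = 0.830), nor was the HER2 amplicon (0.668), in which PGAP3 was at 12.47 ± 0.19 against 12.23 ± 0.08 and was called without brain replicate 4 (0.33, limma adjusted p = 0.0420), as was ORMDL3 (0.40, adjusted p = 0.0126). Of its 14 genes 0 were called over all genes tested or adjusted over the list alone, and 3 had an unadjusted p under 0.05.

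**Figure D3:**
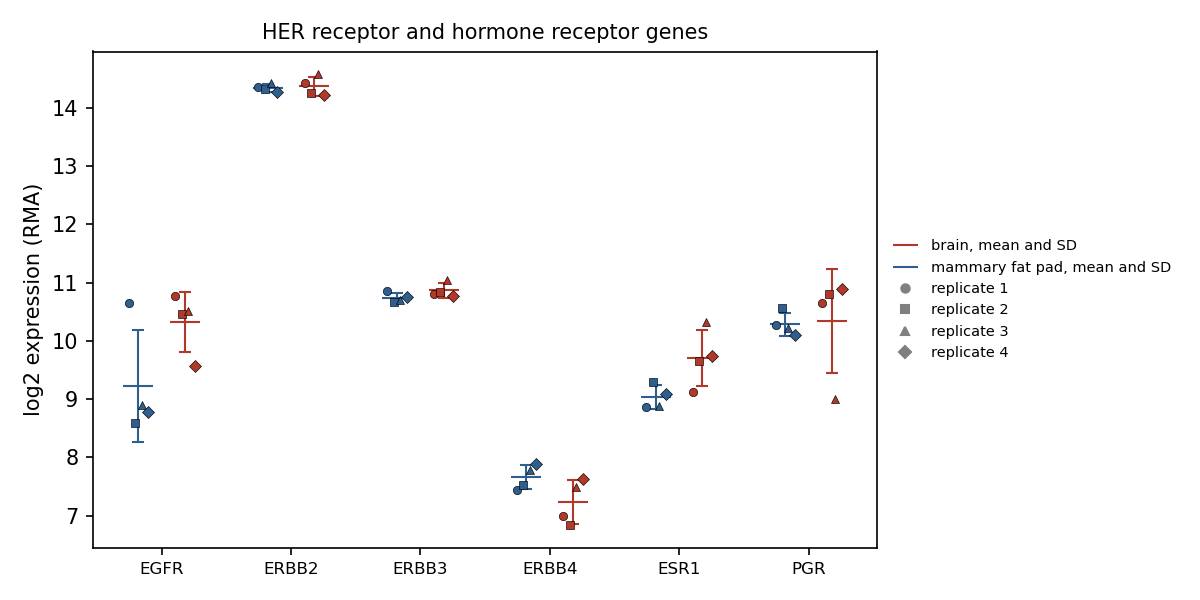
Log2 expression of 4 HER receptor genes and 2 steroid receptor genes, 1 point per array, with the mean and SD of the 4 arrays per site. ERBB2 lay at 14.37 in the brain and 14.35 in the mammary fat pad, both near the top of the array's range. In 1 mammary fat pad array the EGFR value was 10.66, within the brain range.

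Other lists were not called by camera, though single members were. SERPINA1, a protease inhibitor and oestrogen receptor target, rose by 1.26 ± 0.15 (SE, n = 4 per site) in a list of 20 targets (camera adjusted p = 0.867), and differed by -0.11 without probe sets that can bind several transcripts, while another of its probe sets differed by 1.52. The glycolytic enzyme PFKM rose by 0.44 ± 0.08 in its list of 15 (0.108), and the iron exporter SLC40A1 by 0.50 ± 0.09 in a list of 14 metallothionein and iron genes (0.455). In that list 2 genes were higher and 5 lower adjusted over the list alone, with MT2A at 11.98 ± 0.26 against 12.54 ± 0.13 (SD, n = 4), called without brain replicate 4 (-0.64, limma adjusted p = 0.0163). In the unfolded protein response (22 genes, 0.830) SEL1L, which serves degradation of misfolded proteins, rose by 0.65 ± 0.11 and the stress-induced TRIB3 fell by 0.49 ± 0.09. With the mean of all probe sets TRIB3 (-0.37) and SLC40A1 (0.21) were not called. TNC was the only called member among 19 genes that the literature ties to brain metastasis (0.158). Their array means were lower in the brain without overlap (-0.10, exact permutation p = 0.0286, unadjusted). The gap was narrow, with brain replicate 2 at 6.532 and mammary fat pad replicate 3 at 6.544. TNC, at -1.51, weighs heavily in that mean: the median difference of the members was -0.054, with 13 negative and 6 positive. No member was called over all genes tested among FOXO targets (0.273), luminal epithelium (0.997), oxidative phosphorylation (0.108), serine and one-carbon metabolism (0.0815), immediate early genes (0.0815), heat shock proteins (0.830) and ribosomal proteins (0.510). Their counts at an unadjusted limma p under 0.05 were 9, 8, 6, 1, 2, 2 and 0 in this order. Adjusted over the list alone, 3 FOXO targets were higher and 2 lower, 3 luminal genes higher and 2 lower, 1 gene of oxidative phosphorylation was higher and 1 immediate early gene lower. The lists of oestrogen receptor targets and glycolysis each had 1 higher member adjusted over the list alone, the unfolded protein response 1 higher and 2 lower, and the brain metastasis genes 1 lower.

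Several of these lists were called by camera when 1 array was left out or the method was changed. Glycolysis was called higher without mammary fat pad replicate 1 (adjusted p = 5.3e-06) and with array weights (0.0239). FOXO targets were called higher without brain replicate 4 (0.0430), and oxidative phosphorylation higher without brain replicate 3 (0.0262) or mammary fat pad replicate 2 (0.0357). Serine and one-carbon metabolism was called lower without brain replicate 1 (0.0348) or 4 (0.0220). Immediate early genes were called lower without brain replicate 2 (0.0472) or mammary fat pad replicate 2 (0.0049) or 3 (0.0098), after centring on tumour cell genes (0.0083), with the mean of all probe sets (0.025) and without the types that bind several transcripts (0.0233). Brain metastasis genes were called lower without brain replicate 2 (0.0326). With all arrays and an estimated correlation the adjusted p was 0.758 for glycolysis, 0.751 for oxidative phosphorylation and 0.693 for each of the other 4.

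Of all markers of brain, vessel, immune, fat and muscle cells, 1 gene was called. GLUL, the glutamine synthetase of astrocytes, which tumour cells can also express, rose by 0.85 ± 0.16 (SE, n = 4 per site) and was the only called gene of 16 astrocyte markers, also adjusted over the list alone. The list had a camera adjusted p of 0.0707 and was called higher without brain replicate 4 (0.0430) or mammary fat pad replicate 1 (0.0380) or 4 (0.0460), after centring on tumour cell genes (0.0407) and with the mean of all probe sets (0.0245). With an estimated correlation its adjusted p was 0.401. Its array means were higher in the brain without overlap (0.15, exact permutation p = 0.0286, unadjusted). The gap was narrow, with brain replicate 4 at 7.391 and mammary fat pad replicate 1 at 7.382. GLUL and CLU, at 0.78 ± 0.27 (SE) and not called, weigh heavily in that mean. The median difference of the 16 markers was 0.053, with 13 positive and 3 negative. The astrocyte filament GFAP was at 7.42 ± 0.06 against 7.29 ± 0.05 and the water channel AQP4 at 5.56 ± 0.25 against 5.28 ± 0.06 (SD, n = 4), and neither was called, but AQP4 was without brain replicate 4 (0.37, limma adjusted p = 0.0458). GLUL differed by 0.053 without probe sets that can bind several transcripts, read near the bottom of the range, and its other probe sets by 0.79 and 1.12. Its call was lost without brain replicate 1 (limma adjusted p = 0.0749) or 2 (0.105), and without mammary fat pad replicate 1 (0.0660), 2 (0.0920), 3 (0.103) or 4 (0.120). No marker of oligodendrocytes (camera adjusted p = 0.830), neurons (0.455), microglia and macrophages (0.183), endothelium (0.616), adipocytes (0.663) or skeletal muscle (0.0815) was called over all genes tested. At an unadjusted limma p under 0.05 there were 1, 3, 3, 2, 1 and 1 in this order, and adjusted over the list alone 1 neuron marker was higher. The skeletal muscle list was called lower without mammary fat pad replicate 1 (camera adjusted p = 0.0412) or 2 (0.0357) and with the mean of all probe sets (0.0473), where the microglia list was also called lower (0.0498). The oligodendrocyte list had a median difference of 0.045 and a mean of -0.008. SNAP25 of neurons was at 8.76 ± 0.13 against 8.56 ± 0.03, MBP of myelin at 8.09 ± 0.21 against 7.87 ± 0.17, and C1QB of macrophages at 5.62 ± 0.13 against 5.87 ± 0.06. C1QB was called without brain replicate 4 (-0.30, limma adjusted p = 0.0412).

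The 3' minus 5' difference of GAPDH was 0.023 ± 0.077 in the brain and 0.188 ± 0.216 in the mammary fat pad (SD, n = 4, exact permutation p = 0.171), and that of ACTB 0.218 ± 0.073 against 0.381 ± 0.205 (exact permutation p = 0.171). Mammary fat pad replicate 2 had the highest value of both, 0.507 and 0.684. The first principal component held 43.9% of the variance. On it, brain replicates 1 to 3 lay between 15.7 and 22.2, the mammary fat pad arrays between -16.4 and -7.12, and brain replicate 4 at -3.35. Brain replicate 4 correlated with the mammary fat pad arrays at a mean r of 0.9954 and with the other brain arrays at 0.9932, across probe sets, which are not independent replicates.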

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

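The tests of brain replicate 4, of MALAT1 and of the matrix genes were chosen after the results were seen, and the rules on host fibroblasts and on RNA integrity, for brain replicate 4 and for MALAT1, were rewritten with their values known.

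Brain replicate 4 lay closer to the mammary fat pad arrays than to the other brain arrays. Over the 1005 genes called without it, its median position was 0.364, where 0 is the mammary fat pad mean and 1 the mean of brain replicates 1 to 3. Left out likewise, mammary fat pad replicate 1 was at 0.267, the other 3 at 0.007 or less, and brain replicates 1 to 3 at 0.599 to 0.813. Each of these was placed over its own set of called genes and against the mean of the remaining arrays of its site, without brain replicate 4. The positions are thus not on exactly the same scale. Brain replicate 4 lay between the groups in 511 of its 1005 genes and within the range of the mammary fat pad arrays in 299. It lay within the range of brain replicates 1 to 3 in 139, or 13.8% (exact 95% interval 11.8 to 16.1). Mammary fat pad replicate 1, left out in the same way, lay within that brain range in 8.60% (6.94 to 10.5) of its own set of 1012 called genes. The intervals treat the genes of 1 array as independent, so they do not measure the spread between arrays. A mammary fat pad tumour under a brain label thus cannot be told apart from a brain tumour of intermediate profile. By these intervals the shares lie apart, but the position of brain replicate 4 exceeds that of mammary fat pad replicate 1 by less than the mammary fat pad arrays span. A mixture of RNA of both sites may account for it: the best single share, 0.291 brain, left a residual 1.35 times the spread between replicates, which does not decide. Lower RNA integrity stays open: its GAPDH (0.0954) and ACTB (0.297) 3' minus 5' differences were the highest of the 4 brain arrays, the others reaching 0.0593 and 0.262, but below the highest mammary fat pad array (0.507 and 0.684), and a real difference between brain tumours was not tested.

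Probe sets of MALAT1 moved in opposite directions: of 12, 1 was called higher and 2 lower in the brain, the extremes at 1.81 and -3.38 log2. It was the only gene of 24 with 2 or more called probe sets whose called probe sets differed in sign. With the ACTB 3' minus 5' difference as a covariate, 1 of the 12 was still higher and 3 were lower in the brain (adjusted over the 12). The counts were the same for GAPDH and without mammary fat pad replicate 2. Thus RNA integrity, as these control probe sets read it, did not account for the opposite signs. These controls may follow the state of MALAT1 RNA only in part, so RNA integrity as the whole cause is not excluded. As a part of the cause it stays open too, since the difference between the 2 extremes followed ACTB with a correlation of -0.679. Probe sets that bind several transcripts may be the source, but 0 of the 1 MALAT1 probe set of another type was called, which cannot decide. Isoforms that differ between the sites stay open, untested.

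Collagen genes were lower in brain tumours. The mean of all 20 fibroblast and matrix genes differed by -0.380 between the sites (95% interval -0.554 to -0.207), which includes the called collagens. Fewer host fibroblasts should lower those of these genes whose human probe sets bind mouse transcripts, and how well they bind is not known. Of the 20, 4 had a positive difference and 16 a negative one, which cannot decide, so that explanation stays open. A lower expression of these genes in tumour cells was not tested.

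By a Dixon test at the 95% level, single arrays stood apart from the other 3 of their site in 29 of 366 groups of 4 values, where chance gives 18.3, with 9 in mammary fat pad replicate 1, 7 in brain replicate 4 and 6 in brain replicate 3. In mammary fat pad replicate 1 these were the list means of hypoxia response (9.89) and glycolysis (12.36, the others 11.83 to 11.90), and the genes EGFR (10.66), HK2 (11.36), BTC (5.97), PHLPP1 (7.87), ENPP2 (6.12), SOX18 (5.63) and POSTN (5.37). In brain replicate 4 they were HOPX (9.16, the others 10.67 to 10.84), TCAP (8.60), CCNG2 (11.65), CLDN3 (9.72), FADS2 (12.68), PARP9 (8.04) and COL1A2 (8.17). In brain replicate 3 they were PGR (9.003, the others 10.66 to 10.89), HSPE1 (10.73), OLIG1 (6.40), GRIN1 (8.05) and the list means of EMT regulators (7.19) and oxidative phosphorylation (11.79). Brain replicate 2 stood apart for LAMB3 (6.44) and EGR3 (6.48), and brain replicate 1 for SLC40A1 (10.58) and the mean of metallothioneins and iron (9.80). Mammary fat pad replicate 3 did so for that same list (9.78), and mammary fat pad replicate 4 for HSPE1 (10.86) and the mean of EMT regulators (7.22).

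Probe sets without a single gene name lie outside the comparison of genes. Of 13522 tested, 27 were called (limma over all probe sets), 12 higher and 15 lower in the brain. Their differences ran from -3.21 to 1.41 log2.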

How the results depend on the processing

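The exact test on list means was added after the data were seen; all other settings were planned. Without 1 array, 33 to 1005 genes were called and 13 to 110 at 2-fold or more (278 and 43 with all arrays). All 278 kept their direction in these fits, which had to be so because their groups do not overlap. With the replicate number as a block, 188 genes were called (152 of the 278), 48 at 2-fold and 11 lists. The deviations of same-numbered arrays from their site means correlated over 0.1 in 2 of 4 pairs. Those of 1 brain array correlated best with its own number, so the numbers were not taken as pairs. Centring on tumour cell genes gave 844 calls and 103 at 2-fold, but kept only 238 of the 278. It moves the median of all genes by 0.133. The mean of all probe sets gave 183 and 14, leaving out probe sets of several transcripts 147 (of 17100 genes tested) and 25, and array weights 526 and 65. A trend and robust variance gave 25 at 2-fold and ended the calls of 12 of the 20 largest changes (APOD at an adjusted p of 0.117, PIP at 0.119, COL3A1 at 0.0699, ANXA1 at 0.130), a surrogate variable 822 calls and an equal-variance test per gene 0. The cause of these changes was not tested. Median centring, quantile normalization, both dim filters and all probe sets singly kept the count of calls within 1.5 times. Of the 278, 220 stayed called with median centring and 257 with quantile normalization. ANXA1 was among those lost with median centring (limma adjusted p = 0.0502).

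Lists: 0 were called with an estimated correlation and 3 by fry (fatty acid synthesis, basal epithelium, fibroblast and matrix). The adjusted p with an estimated correlation was 0.401 for PI3K components and cholesterol synthesis, 0.174 for ERK output, 0.103 for basal epithelium, 0.330 for EMT regulators, 0.693 for proliferation, hypoxia and interferon, 0.0826 for fatty acid synthesis, 0.529 for MHC class I and 0.270 for fibroblast and matrix. By fry it was 0.155 for PI3K components, EMT regulators and MHC class I, 0.0506 for ERK output, 0.430 for proliferation and hypoxia, 0.0934 for cholesterol synthesis and 0.391 for interferon. With the mean of all probe sets PI3K was at 0.0959. Without 1 array the adjusted p ran from 0.0052 to 0.169 for PI3K, 0.000339 to 0.0541 for EMT regulators, 1.0e-07 to 0.0884 for proliferation and 1.4e-12 to 0.0574 for hypoxia. Of the values of single lists, 25 gained a call and 29 lost one. Gains with the adjusted p: FOXO targets without brain replicate 4 (0.0430), glycolysis without mammary fat pad replicate 1 (5.3e-06) and with array weights (0.0239), oxidative phosphorylation without brain replicate 3 (0.0262) or mammary fat pad replicate 2 (0.0357), serine metabolism without brain replicate 1 (0.0348) or 4 (0.0220) and brain metastasis genes without brain replicate 2 (0.0326). Immediate early genes gained it in 6 settings (0.0049 to 0.0472), astrocyte markers in 5 (0.0245 to 0.0460), skeletal muscle in 3 (0.0357 to 0.0473) and microglia in 1 (0.0498). The unadjusted exact permutation p of list means was 0.0286 for astrocyte markers and brain metastasis genes, 0.0857 for PI3K and interferon, 0.114 for EMT regulators, 0.286 for proliferation and 0.229 for hypoxia.

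EGFR ranged from 0.88 to 1.57 without 1 array (called only without mammary fat pad replicate 1) and was called at 1.23 after centring on tumour cell genes; its 8 other probe sets, none called, were at 0.81, 0.51, 0.41, 0.41, -0.0098, -0.031, -0.84 and -0.87. ESR1, itself in the set used for that centring, was called at 0.81 after it (limma adjusted p = 0.0101). ERBB2 ranged from -0.043 (without brain replicate 3) to 0.074, and 1 other ERBB3 probe set was at -0.082. Without probe sets of several transcripts the sign turned for MALAT1 (-0.35; -0.53 with the mean of all probe sets), HOPX (-0.14), CXCL14 (0.070), COL3A1 (0.09), SERPINA1 (-0.11), IDI1 (-0.024), PARP9 (-0.011) and B2M (-0.034), each then read by another probe set, and SC5D (0.069), FADS2 (0.10), GLUL (0.053) and COL1A2 (-0.13) lost the call. With the mean of all probe sets COL1A1 (-0.18) and POSTN (-0.23) lost it, among others. Further probe sets differed by -1.36 for COL3A1, 1.52 for SERPINA1, 0.47 for IDI1 and 0.55 for B2M, whose replacement lay near the bottom of the range. APOD differed by 2.68 without brain replicate 2 and 3.95 without brain replicate 4, and without brain replicate 4 PIP by 3.48 and ANXA1 by -2.91. Of the other values of named genes, 2224 kept their side of the threshold, 231 lost and 82 gained it. Levels near the bottom of the range, such as POSTN and SNAI2, or near its top, such as ERBB2 and MUCL1, limit what can be seen.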

Other observations

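The split test of list means was chosen after the number of lists was known, and the genes named in the next paragraph were chosen after their values were seen; the 4 further gene lists were chosen after the largest changes were seen but before their members were looked at.

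IL6ST, the signalling chain shared by interleukin 6 family receptors, rose by 1.38 ± 0.22 (SE, n = 4 per site) in brain tumours and IL1R1, the interleukin 1 receptor, by 1.41 ± 0.26, while the neutrophil chemokine CXCL8 fell by 1.16 ± 0.11 and the chemokine receptor ACKR3 by 1.12 ± 0.09. The transcription factor EHF rose by 1.25 ± 0.20 and the claudin CLDN8 by 1.12 ± 0.22, and the mucin MUC5AC fell by 1.22 ± 0.20. S100A6, of the same family as S100A4, fell by 1.13 ± 0.18. ID1, an inhibitor of helix-loop-helix transcription factors, fell by 1.26 ± 0.17. The largest limma adjusted p of these genes was 0.0416, for CLDN8. CXCL8, ACKR3 and ID1 were called whichever array was left out, S100A6 in 4 of these 8 fits, IL6ST and EHF in 3, IL1R1 and MUC5AC in 2 and CLDN8 in 1.

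APOD, PIP, SCGB2A1 and MUCL1 code for secreted proteins, a grouping made after their values were seen. Their rise may reflect a shared regulator, which 4 lists without the genes of largest change were used to test. The mean of 17 androgen receptor targets differed by 0.190 between the sites (95% interval 0.0144 to 0.365), with 12 positive members and 4 higher adjusted over the list alone, but camera did not call the list (adjusted p = 0.129) and MAF fell, by 0.53 ± 0.11 (limma adjusted p = 0.0479, called in 1 of the 8 fits without 1 array), while ACP3 was at 7.81 against 6.93 without being called. The mean of 9 apocrine metabolism genes differed by 0.296 (-0.138 to 0.730), that of 12 glucocorticoid targets by 0.155 (-0.223 to 0.533) and that of 12 JAK-STAT targets by 0.179 (-0.0491 to 0.408). The camera adjusted p of these 3 was 0.129, 0.411 and 0.400, with 0, 1 and 3 members higher adjusted over the list alone. Thus 0 of the 4 lists were called, and each interval reaches past 0.2, the size below which a set shift was to be excluded. The hypotheses stay open, with CEBPD at 8.50 against 7.76 among the JAK-STAT targets not called.

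Other splits of the 8 arrays into 4 and 4 were counted, 35 in all. The real split had the most calls, 278 against at most 58 in another, and the most at 2-fold or more, 43 against at most 12. Only 1 of the 35 splits, the real one, was as large for each. That is the smallest share that 35 splits allow, so chance is unlikely but not excluded. The genes at 2-fold or more are part of the calls, so they are not a second test. For lists called by camera with the preset correlation, 6 splits, the real one included, gave 11 or more, with up to 14, and chance cannot be excluded for that count. For lists whose array means did not overlap, the real split had 8 and the others at most 5, so only 1 was as large. In some of these 8 lists the gap between the sites was narrow, as given above. That count was chosen after its value was known, so it cannot exclude chance.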
